A study of Caenorhabditis elegans with 12 samples.

How the data were processed

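Total RNA from whole L1 larvae was extracted with Trizol, and biotin-labelled cRNA was made from 6 ug of it and hybridised to 1-colour Affymetrix C. elegans arrays, per the labels' protocols. The 12 samples fall by their labels into wild type and manf-1 mutants, each with vehicle and with tunicamycin, 3 arrays per group. The deposited table holds log2 signals for 22625 probe sets on all 12 arrays. That the scale is log2 was read from the values, whose range matches a scanner's range only on that scale. The submitters' processing notes name MAS5 without a role or version. The arrays' medians lay between 3.956 and 4.052 and their quantiles nearly coincide, so the values had been normalized between arrays. The 2% trimmed means of the antilogged signals ranged from 71.53 to 78.01, which is not a common MAS5 target, so the method that made the deposited log2 values remains unknown. A background correction or probe summary that compresses low signals would shrink differences of dim probe sets, and between-array scaling assumes that most transcripts keep their level. The table has no detection calls. No 2 arrays were identical.

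The 77 Affymetrix control probe sets were left out, and no further normalization was applied. Of the 22548 others, 14709 were kept because they exceeded the 40th percentile of their own array on at least 3 arrays. Names came from the platform annotation, with gene numbers looked up in the RefSeq gene table of assembly WBcel235. Of the kept probe sets 13689 have 1 gene, 481 several and 539 none listed, 13649 of those with 1 gene were matched by number, and 0 symbols changed. No gene was named from a probe set with several genes. No build is named for the values, so no coordinates are given. For each of the 10844 genes the kept probe set with the highest mean over all arrays was used, which is a choice for the 2332 genes with more than 1. No probe set is named for manf-1, and its level was not analysed here.

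Group means were fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3, with 8 residual and 5.93 prior degrees of freedom. The 5 contrasts were tested two-sided: tunicamycin in each genotype, genotype in each treatment, and their interaction. Adjusted p is Benjamini-Hochberg within a contrast, over probe sets or over lists, with a threshold of 0.05. Errors are SD over 3 arrays for signals and limma's SE for log2 changes. The 27 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, and again with an estimated one. In the lists that passed, median, mean and test had the same sign. They cover ER chaperones, ER-associated degradation, unfolded protein response sensors, N-glycosylation, ER translocation and export, other stress responses, detoxification, immune effectors, epidermal peptides, lipid metabolism, autophagy, insulin signalling, collagens, ribosome, proteasome, histones, dopaminergic neurons, and markers of 6 tissues. Of the members written into the lists, 12 matched no gene. Adjustment over a list alone is given only for lists that passed in that contrast. It uses the values that picked the list and does not allow for the choice among 27 lists.

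Genes were named by a rule set before the data were examined. It took up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold whose groups did not overlap, with no overlap condition for the interaction. Where fewer than 3 passed in both directions together, it took the 3 smallest p-values in each direction. It added up to 4 members with the smallest p from each list that passed and from 5 fixed lists, and manf-1, hsp-3, hsp-4, xbp-1, ire-1, pek-1 and atf-6. The text gives part of these. A pair of groups of 3 does not overlap by chance in 10% of cases.

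On simulated arrays with the spread of the real ones and 14709 probe sets, the tunicamycin contrast in wild type recovered 4% of 50 probe sets changed 2-fold, 78% of those changed 4-fold and 98% of those changed 8-fold, with 5 false calls among 145. The interaction recovered 18% at 4-fold and 70% at 8-fold, with 5 false calls among 101. In 20 simulated runs over 10844 genes, a list shifted by 0.5 for tunicamycin in wild type was called in all 20, and unshifted lists were called 1 time in 520 tests. Every gene was drawn independently in these runs. The rate of false list calls therefore does not carry over to real lists whose genes vary together.

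Alternatives were quantile normalization, centring on array medians, no filter, a filter at the 60th percentile (10333 probe sets), an offset of 5.08 before log2, eBayes without the trend or robust, fits of only the groups compared, the replicate number as a block, an unadjusted p with a 2-fold change, an unmoderated test, leaving out each array, and for lists the mean over a gene's probe sets. Chosen after seeing the data were the removal of the 4 arrays numbered 2, an additive fit of those 4 alone, the effects averaged over treatments or genotypes, the scan of 293 gene classes and the tests of control probe sets. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.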

Results

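Gene expression was measured in whole first-stage (L1) larvae of the nematode Caenorhabditis elegans, in the wild-type strain N2 and in manf-1 mutants carrying the tm3603 allele. MANF-1 is the worm homologue of MANF and CDNF, secreted and endoplasmic reticulum (ER) resident proteins with a neurotrophic role in vertebrates. Eggs hatched on plates without food, and the synchronized larvae were collected 24 h after plating and then kept for 5 h in vehicle (DMSO) or in tunicamycin. Tunicamycin blocks the opening step of N-linked glycosylation, so that misfolded glycoproteins accumulate in the ER and the unfolded protein response is engaged. The labels give the dose with the number 5 and disagree on its unit, which is ug per mL in the sample characteristics and ug per uL in the treatment description. Each of the 4 combinations of genotype and treatment had 3 arrays, 12 in all, and the number of arrays limits the precision of every value. Values are log2 signals of Affymetrix probe sets, of which 14709 entered the tests. The array's background-like control probe sets had a median of 2.22 and a 95th percentile of 3.35 on the same scale. No probe set is named for manf-1 itself, so the level of the mutated gene, which would check the genotype labels, was not analysed here.

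Arrays of 1 group had Spearman correlations between 0.848 and 0.927. The median SD over probe sets was 0.434 in wild type with vehicle, 0.469 in wild type with tunicamycin, 0.400 in mutants with vehicle and 0.373 in mutants with tunicamycin. The arrays numbered 2 stood apart from the rest in signal along transcripts. The mean difference between 3′ and 5′ probe sets of 5 control transcripts was between -0.32 and -0.20 on the 4 arrays numbered 2 and between 0.02 and 0.38 on the other 8. This difference was -0.01 ± 0.18 (SD, n = 6) with tunicamycin and 0.04 ± 0.26 (SD, n = 6) with vehicle. The treatments did not differ in this mean by a two-sided exact permutation test (p = 0.66). Opposite shifts of single transcripts cancel in it, so it cannot show that each was unaffected. With tunicamycin the 3′ and 5′ probe sets of 1 transcript changed by 0.56 and 1.16, and those of another by -0.14 and -0.5. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples. In the 4 arrays numbered 2 alone, an additive limma fit of treatment and genotype with 1 residual degree of freedom, chosen after seeing the data, gave a tunicamycin effect of 3.86 (SE 0.37, adjusted p = 0.121) for hsp-4 and a genotype effect of -3.24 (SE 0.63, adjusted p = 0.996) for tag-244. In that fit 1 probe set passed for tunicamycin and 0 for genotype, with 770 and 678 at an unadjusted p under 0.05.

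The comparison of tunicamycin with vehicle in wild type asks which transcripts respond to blocked glycosylation. ER chaperones and folding enzymes rose together, with 12 of 18 measured genes past the threshold, none lower, and a median log2 change of 2.17. The signal of hsp-4, a worm homologue of the ER Hsp70 chaperone BiP, rose from 8.24 ± 0.75 to 11.46 ± 0.21 (SD, n = 3 each), a log2 change of 3.22 (SE 0.30, limma adjusted p = 0.000142). The other BiP homologue, hsp-3, rose by 1.81 (SE 0.19, adjusted p = 0.000345) from 9.62 ± 0.18 to 11.43 ± 0.24 (SD, n = 3 each). Among protein disulfide isomerases, C14B9.2 rose by 2.46 (SE 0.27), pdi-2 by 2.20 (SE 0.27) and pdi-6 by 2.86 (SE 0.50). A second pdi-2 probe set was at 1.22 with an adjusted p of 0.139. Among the probe sets used, 1 per gene and each with a single gene, the largest rise belonged to ckb-2, a choline kinase of phospholipid synthesis. It was 4.82 (SE 0.34, adjusted p = 1.43e-05), which is 28.2-fold. Next among these were gfat-1, the entry enzyme of the hexosamine pathway that feeds glycosylation, at 4.01 (SE 0.53), and dpy-18, a collagen prolyl 4-hydroxylase subunit, at 3.29 (SE 0.39). The other dpy-18 probe sets were at 3.53 (adjusted p = 0.00209) and 2.27 (adjusted p = 0.0523). The genes calu-1, a calumenin, Y41C4A.32 and warf-1 rose by 3.28, 3.16 and 3.06.

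**Figure D1:**
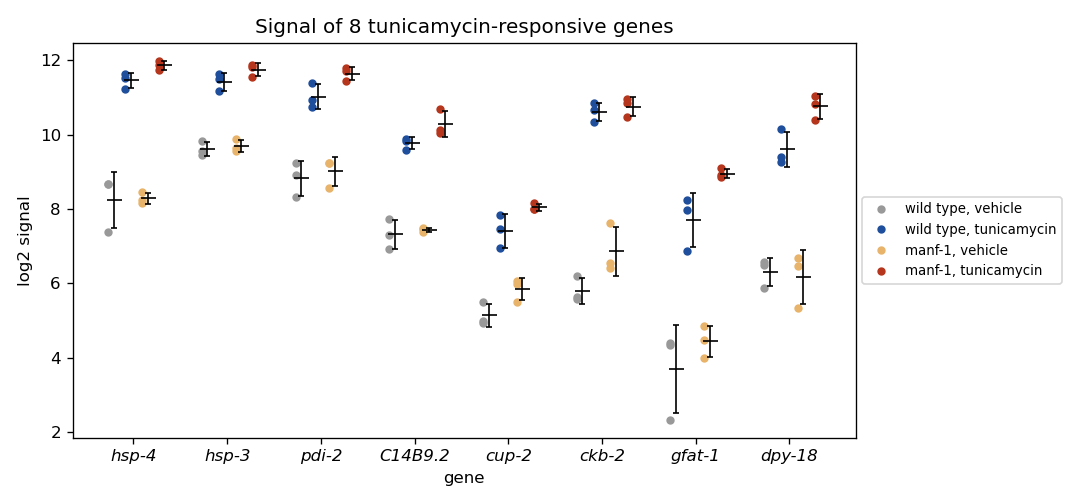
Log2 signal (vertical axis) of 8 genes (horizontal axis) on each of the 12 arrays, coloured by genotype and treatment; points are arrays, and the black dash and bar beside them are the group mean and SD (n = 3). For hsp-4 the tunicamycin means of 11.46 in wild type and 11.86 in mutants lie above the vehicle means of 8.24 and 8.29.

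ER-associated degradation genes rose as a list in wild type, with a median log2 change of 0.48 and 2 of 17 genes past the threshold. These were cup-2, a derlin homologue, at 2.28 (SE 0.34, adjusted p = 0.00665), and ubxn-4, a cofactor of the CDC-48 segregase, at 1.87 (SE 0.35, adjusted p = 0.0339). Genes of ER translocation and COPII vesicle export had a median change of 0.75, with 1 of 19 past the threshold, the signal peptidase subunit spcs-1 at 2.12 (SE 0.34, adjusted p = 0.00954). For that list the adjusted p was 0.0511 with an estimated correlation. The N-glycosylation genes had a median of 0.52 with 0 of 17 past the threshold, and the list an adjusted p of 0.138 with an estimated correlation. Among them, algn-7, the worm homologue of the enzyme that tunicamycin inhibits, had a change of 2.05 (SE 0.42, adjusted p = 0.0554). The list of unfolded protein response sensors and transducers had a median of 0.83, with 0 of 9 past the threshold and an adjusted p of 0.138 with an estimated correlation. Its members xbp-1, pek-1, ire-1 and atf-6 had changes of 1.02, 0.86, 0.83 and 1.02, with limma adjusted p-values of 0.111, 0.674, 0.749 and 0.795. Second probe sets gave 0.39 for xbp-1, 1.04 for pek-1, 0.26 for ire-1 and -0.14 for atf-6, so the size for xbp-1 and ire-1 and the sign for atf-6 were not settled.

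In the other direction, collagens, the cuticle's structural proteins, had a median change of -0.31 in wild type, with 111 of 126 values below 0 and 0 past the threshold singly. The hypodermis markers had a median of -0.53 with 17 of 20 values below 0, and the intestine markers a median of -0.18 with 12 of 17 below 0. For these lists the adjusted p with an estimated correlation was 0.219, 0.138 and 0.241. The values of single members did not pass: col-41 was at -1.80 (adjusted p = 0.0729), wrt-2 at -1.49 (adjusted p = 0.477) and asp-1, an aspartyl protease, at -1.26 (adjusted p = 0.104). The genes that fell singly included drd-1, by 3.32 (SE 0.55, adjusted p = 0.013) to a treated signal of 2.73, below the background controls' 95th percentile, and grl-7, a ground-like protein gene, by 3.31 (SE 0.59, adjusted p = 0.0202). A second grl-7 probe set was at -1.59 with an adjusted p of 0.315. The lysozyme lys-1 was at -1.43 (adjusted p = 0.207).

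By limma, 58 probe sets passed in wild type, 53 higher (42 named genes) and 5 lower (3 named genes), and 1179 had an unadjusted p under 0.05 where 735 would by chance. Of the 27 lists, 8 passed limma's camera test, 5 up and 3 down. With an estimated correlation 2 of these held: the chaperones (adjusted p = 0.0265) and ER-associated degradation (adjusted p = 0.034). Without single wild-type arrays the sensors (vehicle array 1, adjusted p = 0.0588, and tunicamycin array 2, 0.0522), N-glycosylation (tunicamycin array 2, 0.0522, and vehicle array 3, 0.112) and intestine markers (vehicle arrays 1 and 3, 0.0868 and 0.137, tunicamycin arrays 2 and 3, 0.0512 and 0.236) did not pass. Adjusted over the list alone, 14 chaperone genes, 5 degradation genes, 6 translocation and export genes, 2 sensors (xbp-1 and zip-10) and 1 N-glycosylation gene (algn-7) passed upward, and 1 collagen (col-41), 1 intestine marker (asp-1) and 0 hypodermis markers downward. The count of probe sets was 20 when only the 6 wild-type arrays were fitted and 35 without the 4 arrays numbered 2, a setting chosen after seeing the data. The calls of warf-1, gfat-1, pdi-6, drd-1, grl-7, cup-2, ubxn-4 and spcs-1 were lost under at least 1 alternative, where their highest adjusted p ranged from 0.0583 for warf-1 to 0.241 for grl-7.

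The same comparison in manf-1 mutants asks whether larvae labelled as mutants mount the response. ER chaperones and folding enzymes rose here too, with 13 of 18 genes past the threshold and a median log2 change of 2.16. The signal of hsp-4 rose by 3.57 (SE 0.30, limma adjusted p = 3.34e-05), from 8.29 ± 0.15 to 11.86 ± 0.12 (SD, n = 3 each), and that of hsp-3 by 2.06 (SE 0.19, adjusted p = 5.1e-05). The disulfide isomerases C14B9.2 and pdi-2 rose by 2.84 (SE 0.27) and 2.63 (SE 0.27), and the second pdi-2 probe set was at 1.16 with an adjusted p of 0.0923. The largest rises among the probe sets used were those of Y41C4A.32 at 5.82 (SE 0.30, adjusted p = 2.43e-07), warf-1 at 5.27 (SE 0.41) and dpy-18 at 4.60 (SE 0.39). They were followed by gfat-1 at 4.52, lips-11, a lipase-related gene, at 4.21, Y54G2A.18 at 4.14, zipt-7.1, a zinc transporter, at 3.97 and ckb-2 at 3.89. The vehicle signal of lips-11 was 2.12, within the range of the background controls, so its change has no measured lower level.

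ER-associated degradation in mutants had a median change of 1.16 with 4 of 17 genes past the threshold. These included cup-2 at 2.20 (SE 0.34), ubxn-4 at 1.88 (SE 0.35), sel-11, a homologue of the ubiquitin ligase HRD1, at 1.80 (SE 0.35) and its partner sel-1 at 1.61 (SE 0.36, adjusted p = 0.0499). Second probe sets of sel-11 and sel-1 were at 0.96 and 1.68 with adjusted p-values of 0.574 and 0.238. ER translocation and COPII export had a median of 1.11, with all 19 values above 0 and 5 past the threshold, among them spcs-1 at 2.33, the coat subunit sec-23 at 2.33, tfg-1 at 1.95 and spcs-3 at 1.57. A second sec-23 probe set was at 2.03 with an adjusted p of 0.108. N-glycosylation genes had a median of 0.40, and 1 of 17 passed: uggt-1, the glucosyltransferase that recognises misfolded glycoproteins, at 1.66 (SE 0.37, adjusted p = 0.0478), which the chaperone list also holds. Its other probe sets were at 0.91 and 1.42, with adjusted p-values of 0.455 and 0.081. The list of sensors and transducers did not pass in mutants (median 0.26, adjusted p = 0.0948). Its members ire-1, xbp-1, atf-6 and pek-1 were at 1.34, 0.87, 0.64 and 0.26, with adjusted p-values of 0.374, 0.133, 0.897 and 0.951, and atf-6 was at -0.19 without mutant vehicle array 2. Their second probe sets were at 0.89, 0.69, 1.04 and 0.28, and none passed. Averaged over both genotypes, a fit chosen after seeing the data, the xbp-1 probe set used rose by 0.94 (SE 0.17, limma adjusted p = 0.00847).

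Of the mutant calls 61 of 158 were lower, and 8 lists moved down by camera. Of these 8, cytochrome P450 (adjusted p = 0.025), immune effectors (0.00787) and lipases (0.0178) held with an estimated correlation, while the adjusted p with it was 0.112 for collagens, epidermal peptides, intestine and hypodermis and 0.161 for histones. The intestinal intermediate filament gene ifc-1 fell by 3.04 (SE 0.34, adjusted p = 0.000237), the aspartyl protease asp-13 by 2.74 (SE 0.36) and pud-4 by 2.73 (SE 0.36), from 8.92 ± 0.46 to 6.19 ± 0.47 (SD, n = 3 each). Further falls were those of pud-3 by 2.79, drd-1 by 2.79, Y16B4A.2 by 2.72, T16G1.6 by 2.71 and ZK512.7 by 2.67. The treated signals of drd-1 and ZK512.7 were 2.57 and 2.76, within the background controls' range, and a second ZK512.7 probe set was at -1.29 with an adjusted p of 0.233. Collagens had a median change of -0.47, with 6 of 126 lower and 1 higher past the threshold. The fall of col-176 was 2.18 (SE 0.36), that of col-125 was 0.88 (SE 0.14), and col-89 rose by 2.52 (SE 0.39). Lysozymes, C-type lectins and other immune effectors had a median of -0.18, with 1 of 116 past the threshold, the lectin clec-52, which fell by 1.85 (SE 0.36, adjusted p = 0.0219), while spp-1 was at -0.93 (adjusted p = 0.123). Lysosomal lipases and beta-oxidation genes had a median of -0.49 with 0 of 14 past the threshold and lipl-3 at -1.60 (adjusted p = 0.0661). Cytochrome P450 and UDP-glucuronosyltransferase genes had a median of -0.29 with 0 of 86 past the threshold and cyp-34A9 at -1.54 (adjusted p = 0.12). Histones had a median of -0.51, with 24 of 25 values below 0, none past the threshold, and his-64 at -0.75 (adjusted p = 0.0815). Epidermal antimicrobial peptides had a median of -0.31 with nlp-33 at -0.86 (adjusted p = 0.0872). Beside these lists, the hypodermis markers had a median of -0.54, with wrt-10 at -1.80 (adjusted p = 0.13), and the intestine markers a median of -0.35, with cpr-6 at -0.94 (adjusted p = 0.317).

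**Figure D2:**
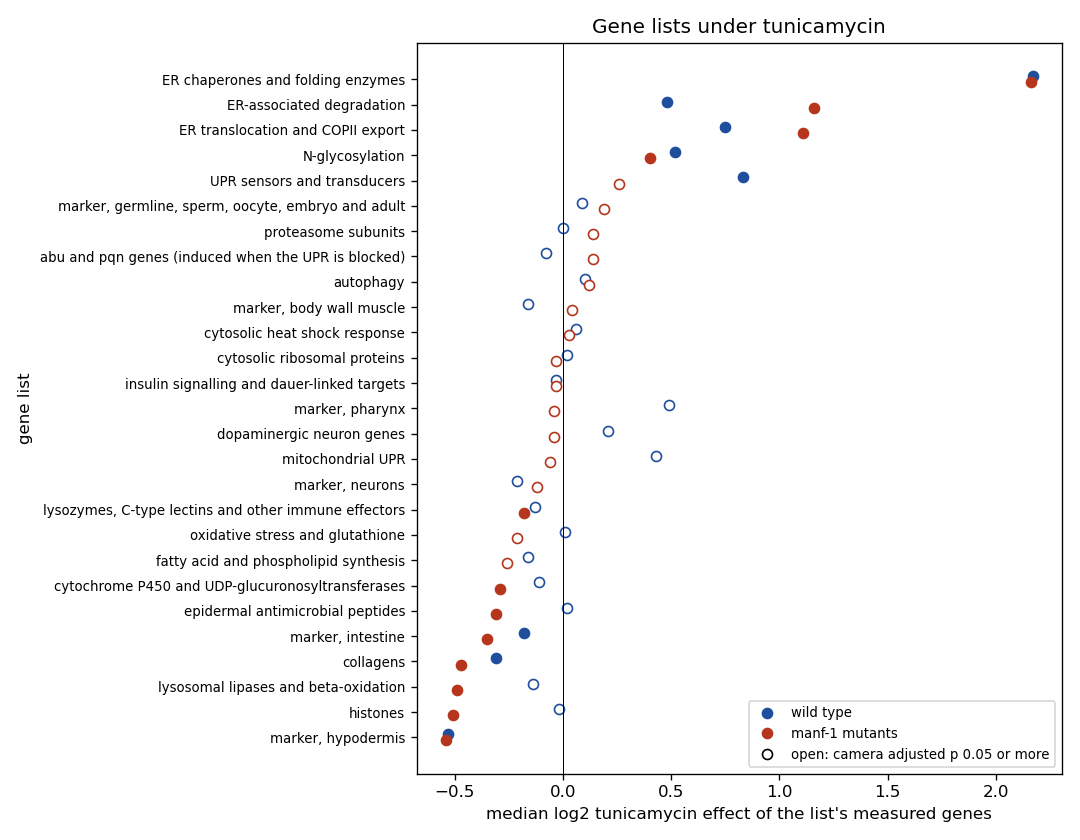
Median log2 tunicamycin effect (horizontal axis) of the measured genes of 27 gene lists (vertical axis) in wild type and in manf-1 mutants; filled points passed limma's camera test with the preset correlation. The chaperone list lies at 2.17 in wild type and 2.16 in mutants, and the degradation list at 0.48 and 1.16.

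In mutants 158 probe sets passed by limma, 97 higher (82 named genes) and 61 lower (49 named genes), with 1307 at an unadjusted p under 0.05. Of the 12 lists that passed, 7 held with an estimated correlation: the 3 lower ones named above, chaperones (adjusted p = 0.00666), degradation and export (both 0.00351) and N-glycosylation (0.0446). Adjusted over the list alone, 15 chaperone, 9 degradation, 13 export and 3 N-glycosylation genes passed upward, with 1 collagen and 1 epidermal peptide, and 20 collagens, 6 immune effectors, 4 epidermal peptides, 2 lipases and 2 histones downward. The count of probe sets was lower without any 1 of the 6 mutant arrays: 79, 98 and 102 without vehicle arrays 1, 2 and 3, 84 and 85 without tunicamycin arrays 2 and 3, and least reduced without tunicamycin array 1. It was 76 without the 4 arrays numbered 2. Lower calls numbered between 20 (without vehicle array 1) and 40 without any 1 mutant array, and 21 without the arrays numbered 2. At an unadjusted p with a 2-fold change there were 349 lower probe sets in wild type and 399 in mutants, and the difference in lower calls between the genotypes was not tested. Without mutant vehicle array 2 the cytochrome P450 list (adjusted p = 0.0518) and the epidermal peptides (0.0756) did not pass, nor without all 4 arrays numbered 2 (0.0745 and 0.138). The calls of pud-3, drd-1, Y16B4A.2, T16G1.6, ZK512.7, cup-2, ubxn-4, sel-11, sel-1, uggt-1, spcs-3, tfg-1, clec-52, col-89, col-125 and col-176 were lost under at least 1 alternative, with a highest adjusted p of 0.282, for sel-1.

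Lists that passed in neither genotype under tunicamycin were those of other stress pathways and cell types. Median log2 changes in wild type and mutants were 0.06 and 0.03 for the cytosolic heat shock response, 0.43 and -0.06 for the mitochondrial unfolded protein response, and 0.01 and -0.21 for oxidative stress and glutathione genes. They were -0.08 and 0.14 for abu and pqn genes, 0.10 and 0.12 for autophagy, -0.03 and -0.03 for insulin signalling targets, and -0.16 and -0.26 for fatty acid and phospholipid synthesis, the list that holds ckb-2. Ribosomal proteins had 0.02 and -0.03, and proteasome subunits 0.00 and 0.14. Dopaminergic neuron genes, of which 7 were measured, had 0.21 and -0.04, neuron markers -0.21 and -0.12, body wall muscle -0.16 and 0.04, pharynx 0.49 and -0.04, and germline and adult markers 0.09 and 0.19. The camera adjusted p of these lists in either genotype was 0.0504 or more.

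Setting the responses side by side, 48 probe sets were higher in both genotypes where 0.35 would be shared by independent lists of 53 and 97. Among the lower calls 3 were shared where 0.0207 would be. Of the 97 higher calls in mutants, 95 also had a positive change in wild type, and 58 of the 61 lower calls had a negative one. The 2 effects share no array. The calls are still not independent, since both contrasts use 1 estimate of the spread per probe set and some genes have more than 1 probe set. The numbers for independent lists are therefore only a rough reference. Over the 280 probe sets that passed for the mean of both effects, the major axis slope of mutant against wild type was 1.27 (jackknife SE 0.207), and it lay between 1.13 and 1.33 when single arrays were left out. Fewer than 280 probe sets passed without any 1 of the 12 arrays, 167 without mutant tunicamycin array 3 and slightly fewer without mutant vehicle array 1, and 46 to 95 lower ones passed in place of 108. The change was larger in mutants for 206 of the 280, and for 124 to 179 probe sets, between 61% and 77.9%, without 1 array. The fewest were 124 without mutant tunicamycin array 3, 126 without mutant vehicle array 1 and 128 without wild-type vehicle array 3. The slope was 1.18 (jackknife SE 0.16) over the 172 higher and 1.63 (jackknife SE 0.57) over the 108 lower probe sets, so none of the 3 slopes differed from 1 by more than 2 of its SE. Across all 14709 probe sets, which are not independent replicates, Pearson's r between the effects was 0.309 and Spearman's rho 0.203.

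**Figure D3:**
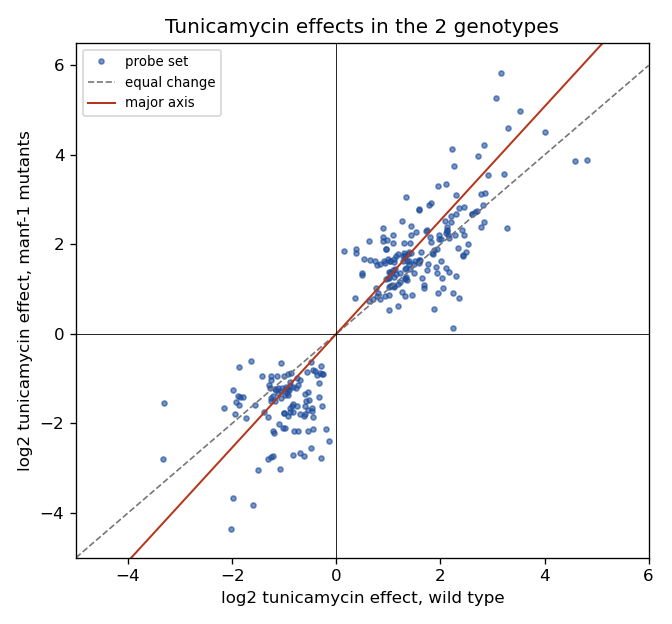
Log2 tunicamycin effect in manf-1 mutants (vertical axis) against wild type (horizontal axis) for the 280 probe sets that passed for the mean effect; each point is a probe set, the dashed line is equal change and the solid line the major axis. The solid line has a slope of 1.27, and 206 of the 280 probe sets had the larger change in mutants (between 61% and 77.9% of those passing when 1 array was left out).

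The comparison of mutants with wild type in vehicle asks how the mutant strain differs without added stress. The gene tag-244 was lower in mutants, at 2.88 ± 0.32 against 6.81 ± 0.43 (SD, n = 3 each), a log2 difference of -3.93 (SE 0.44, limma adjusted p = 0.00628), and the mutant signal lay within the background controls' range. The BiP homologues had small differences that did not pass, 0.05 (SE 0.30) for hsp-4, which was -0.36 without the arrays numbered 2, and 0.07 (SE 0.19) for hsp-3, and xbp-1 was at 0.42 (SE 0.24) with a second probe set at -0.08. The next smallest p-values did not pass either: T07F12.4 was at 2.21 and gem-4 at 1.61, and B0454.5 at -2.32 and Y25C1A.8 at -1.64, with adjusted p-values between 0.437 and 0.807. Fatty acid and phospholipid synthesis genes moved up by camera, with a median of 0.16, 20 of 25 values above 0 and 0 past the threshold, but had an adjusted p of 0.78 with an estimated correlation. Among them nhr-49, a nuclear receptor of fat metabolism, was at 1.09 (adjusted p = 0.888), with a second probe set at 0.00. Collagens moved down, with a median of -0.14 and 85 of 126 values below 0, and also had an adjusted p of 0.78 with an estimated correlation. The collagen col-41 was at -1.34 (adjusted p = 0.888). Adjusted over the list alone, 0 genes of these 2 lists passed.

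Of the 14709 probe sets, 1 passed by limma in this comparison, 769 had an unadjusted p under 0.05 where 735 would by chance, and the test without moderation called 0. The tag-244 call was lost without wild-type vehicle array 1 (adjusted p = 0.0582) or mutant vehicle array 2 (adjusted p = 0.0505), and without all 4 arrays numbered 2 (0.627), with log2 differences of -3.70, -3.99 and -4.02 in these fits. Its adjusted p ranged from 0.00174 to 0.627 over the alternatives. Fatty acid synthesis did not pass without wild-type vehicle array 1 (0.183) or mutant vehicle arrays 2 (0.0519) and 3 (0.431), collagens without mutant vehicle array 2 (0.502) or wild-type vehicle array 3 (0.175), and neither without the 4 arrays numbered 2. The chaperone list had a median of 0.20 (adjusted p = 0.385), the degradation list 0.10 (0.693) and dopaminergic genes 0.20 (0.629).

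Under tunicamycin, 6 probe sets separated mutants from wild type. Lower in mutants were tag-244, at 2.70 ± 0.29 against 5.6 ± 0.92 (SD, n = 3 each) with a log2 difference of -2.90 (SE 0.44), T22F3.11, at 8.37 ± 0.59 against 10.40 ± 0.48 with -2.03 (SE 0.31), and alh-5, an aldehyde dehydrogenase family gene, at 5.81 ± 0.05 against 7.61 ± 0.25 with -1.79 (SE 0.28). Each had a limma adjusted p of 0.0495, and a second T22F3.11 probe set was at -2.19 with an adjusted p of 0.0186. The remaining lower probe set is assigned to several genes. The higher probe set is 1 of 3 for rab-6.1, a Rab GTPase of Golgi traffic, and was singled out after its values were seen. The chaperones hsp-4 and hsp-3 had differences of 0.40 (SE 0.30) and 0.33 (SE 0.19) that did not pass.

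By camera 4 lists moved up in mutants under tunicamycin, with medians of 0.36 for chaperones, 0.51 for ER-associated degradation, 0.43 for ER translocation and export and 0.29 for proteasome subunits. With an estimated correlation their adjusted p was 0.368, 0.0651, 0.164 and 0.437. N-glycosylation genes and sensors, with medians of 0.20 each, did not pass. In the lists that moved up 0 genes passed singly: pdi-2 was at 0.63, sel-11 at 0.88 and trap-2 at 1.04, with second probe sets at 0.08, 0.31 and -0.16. Downward lists were epidermal antimicrobial peptides with a median of -0.49, collagens with -0.30, histones with -0.23, cytochrome P450 and UDP-glucuronosyltransferases with -0.13 and pharynx markers with -0.67. With an estimated correlation their adjusted p was 0.0651, 0.282, 0.368, 0.0651 and 0.192. Their members nlp-33, col-165, his-61 and myo-5 were at -0.68, -1.87, -0.56 and -2.40, and the immune effector spp-1 at -0.95, with adjusted p-values between 0.345 and 0.769. Adjusted over the list alone, on the values that had picked the lists, myo-5 passed and 0 genes of the other 8 lists did. In this contrast the intestine and hypodermis markers had medians of -0.24 and -0.23 and did not pass.

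**Figure D4:**
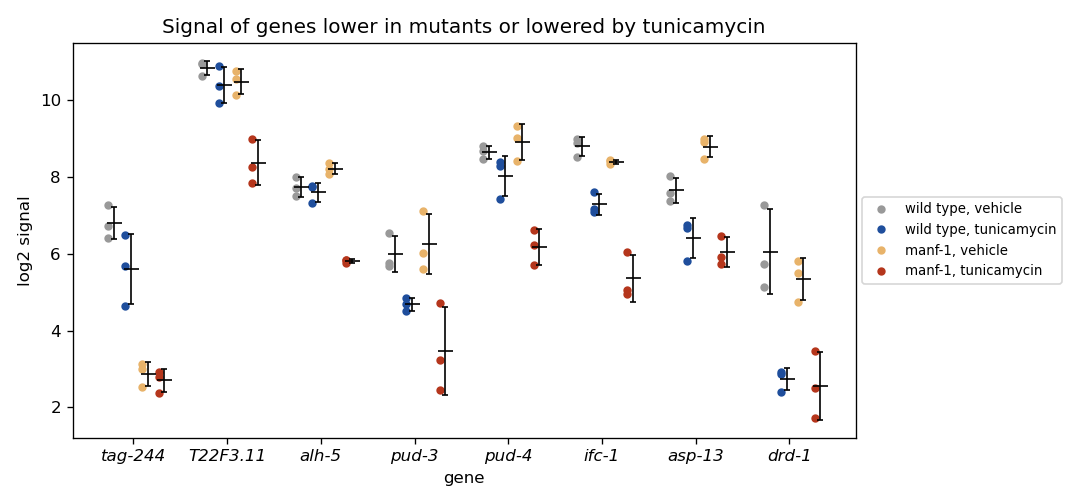
Log2 signal (vertical axis) of 8 genes (horizontal axis) on each of the 12 arrays, coloured by genotype and treatment; points are arrays, and the black dash and bar are the group mean and SD (n = 3). The tag-244 means of the mutants are 2.88 with vehicle and 2.70 with tunicamycin, against 6.81 and 5.6 in wild type.

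By limma, 810 probe sets had an unadjusted p under 0.05 for this genotype difference, where 735 would by chance. The 6 calls lie close to the threshold: leaving out any 1 of the 12 arrays gave between 0 and 3 calls, and leaving out the 4 numbered 2 gave 0. Not all of those calls were among the 6: without wild-type tunicamycin array 2 there was 1 call, and it was a different probe set. For the probe sets used, the alh-5 call was lost without any 1 of the 12 arrays. That of T22F3.11 was kept only without mutant tunicamycin array 3, and that of tag-244 only without wild-type tunicamycin array 3. Quantile normalization and median centring each gave 5, all lower, so the rab-6.1 probe set did not pass under either scaling. Without wild-type tunicamycin array 3 the chaperones (adjusted p = 0.125), export (0.0508), histones (0.0905), proteasome (0.19) and cytochrome P450 (0.0905) lists did not pass. The proteasome list was also lost without mutant tunicamycin array 1 (0.117) or wild-type array 2 (0.0544), and cytochrome P450 without wild-type array 2 (0.185) or mutant arrays 2 (0.0584) and 3 (0.097), or without the 4 arrays numbered 2 (0.26). The adjusted p of tag-244 reached 0.433 over the alternatives, that of T22F3.11 0.483 and that of alh-5 0.433. In the fits without arrays that lost these calls the log2 differences were between -3.01 and -2.46 for tag-244, between -2.26 and -1.77 for T22F3.11 and between -1.94 and -1.70 for alh-5.

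The interaction tests directly whether the tunicamycin effect differs between the genotypes. The genes that mark the response had similar effects in both: the difference, mutant minus wild type, was 0.35 (SE 0.42) for hsp-4 and 0.25 (SE 0.27) for hsp-3, each with a limma adjusted p of 0.995. With the SE of these estimates a moderate difference in either direction is not excluded. Among the probe sets used, 1 per gene, the smallest p-values upward and downward included those of Y41C4A.32 at 2.66 (SE 0.42, adjusted p = 0.0974), rmd-1 at 3.25 (SE 0.67, adjusted p = 0.494), alh-5 at -2.27 (SE 0.40, adjusted p = 0.233) and F21G4.5 at -2.76 (SE 0.50, adjusted p = 0.235), which did not pass. A second T22F3.11 probe set was at -2.47 (adjusted p = 0.0974) and did not pass either. ER translocation and export genes moved up by camera with a median difference of 0.54 and 16 of 19 values above 0, histones moved down with -0.36 and 20 of 25 below 0, and epidermal antimicrobial peptides moved down with -0.44 and 15 of 19 below 0. Adjusted p with an estimated correlation was 0.349 for export and epidermal peptides and 0.462 for histones. In them trap-2 was at 1.34, with a second probe set at -0.49, his-64 at -0.93 and abf-2, an antibacterial factor, at -2.23, none past the threshold. Adjusted over the list alone, on the values that had picked the lists, abf-2 passed and 0 genes of the other 2 lists did. The chaperone list had a median difference of 0.15 (adjusted p = 0.25) and the degradation list 0.27 (adjusted p = 0.147).

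A single probe set passed the interaction by limma, the rab-6.1 probe set named above, and 679 had an unadjusted p under 0.05 where 735 would by chance. Its difference was 3.73 (SE 0.46, adjusted p = 0.0177). The other 2 probe sets of rab-6.1 were at -0.33 and 0.15. The call was lost without any 1 of 9 of the 12 arrays, that is all but wild-type vehicle array 1, wild-type tunicamycin array 1 and mutant vehicle array 2. The median SE of an interaction was 0.586 against 0.414 for the other contrasts, so fewer differences could be detected. Without the 4 arrays numbered 2 no probe set passed, nor did the export list (adjusted p = 0.0704) or the epidermal peptides (0.0689). Without wild-type tunicamycin array 3 none of the 3 lists passed (adjusted p = 0.0716 for export and histones and 0.194 for epidermal peptides). The epidermal peptides were also lost without wild-type vehicle arrays 1 (0.097) and 3 (0.0868), mutant vehicle array 2 (0.101) or mutant tunicamycin array 2 (0.0711).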

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

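The tests of the tag-244 locus, of T22F3.11 with alh-5, of the slope of the mutant response, of the genotype effect averaged over treatments, of the control probe sets and without the arrays numbered 2 were chosen only after the data or the results were seen.

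A probe set of rab-6.1, 1 of 3 for that gene, differed between genotypes in its tunicamycin effect by 3.73 on the log2 scale (limma adjusted p = 0.0177), falling by 1.98 in wild type and rising by 1.75 in mutants. Among 100 drawn splits of the arrays between genotypes within each treatment, 5 gave at least 1 interaction call, the real one included, and the highest other gave 2, so chance is not excluded for this count. Lists whose tunicamycin effect differed between genotypes in the same test were ER translocation and export (median 0.54), epidermal antimicrobial peptides (median -0.44) and histones (median -0.36), with adjusted p-values of 0.349, 0.349 and 0.462 with an estimated correlation. Of the 100 splits 45 gave at least 3 lists and the highest other gave 10, so chance is not excluded for them.

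Among the 77 control probe sets, which were left out of the gene comparisons and served only for the difference between 3′ and 5′ signal and the background level, 3 for 1 control transcript had a higher signal in the 6 tunicamycin arrays than in the 6 vehicle arrays, by 1.37 (from 5.16 ± 0.91 to 6.53 ± 0.34), 1.16 (from 7.67 ± 0.43 to 8.84 ± 0.46) and 1.03 (from 7.1 ± 0.39 to 8.13 ± 0.51, SD), each with an adjusted p of 0.0476 in a two-sided exact permutation test. The fourth probe set of that transcript was at 0.56 (from 7.09 ± 0.43 to 7.65 ± 0.25, SD) and did not pass (adjusted p = 0.104). In group means, the probe set at 1.37 went from 4.47 to 6.71 in wild type and from 5.86 to 6.35 in mutants. The fourth went from 7.41 to 7.54 in wild type and from 6.77 to 7.75 in mutants. A further 4 control probe sets passed the same test with a lower signal, with differences from -0.54 to -0.25. All that passed belong to worm control transcripts of the array. Of the bacterial and phage controls (bioB, bioC, bioD and cre) none passed, with a lowest adjusted p of 0.69. The test pools the genotypes, so shifts of opposite sign cancel in it. In group means a bioC probe set went from 10.97 to 11.38 in wild type and from 11.35 to 11.2 in mutants. A bioB probe set went from 9.26 to 9.53 and from 9.56 to 9.3. A bioD probe set rose in both, from 12.9 to 13.14 and from 12.99 to 13.08. Whether these controls shifted differently in the 2 genotypes was not tested.

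Averaged over treatments, tag-244 and C34H4.1 were the 2 probe sets that passed for genotype, lower in mutants with log2 differences of -3.41 (SE 0.31) and -2.49 (SE 0.35). With the 2 smallest p-values chosen anew without each array, tag-244 was chosen all 12 times and all 12 left-out arrays lay on their own genotype's side, which argues against a few poor arrays for it. They stay open for C34H4.1, chosen 6 times with 5 arrays on their own side, whose call was kept without wild-type tunicamycin array 2 or 3 and lost without any other 1 array (adjusted p from 0.0546 to 0.163, differences from -2.55 to -2.41). The genes lie 2 protein-coding genes apart and 191 and 189 such genes from manf-1 on the same chromosome, and a share of 0.000236 of random pairs of measured genes lie as close, as a sequence variant or deletion carried with the mutant strain would need. The mutant mean of tag-244 was 2.79, below the background controls' 95th percentile of 3.35, and that of C34H4.1 was 3.62, above it. A background control averaged 3.69 in wild type with vehicle and 3.44 and 3.39 in the mutant groups. The mutant signal of C34H4.1 is thus not clearly set apart from these controls. None of 10 measured neighbours passed (between -0.36 and 0.46). This leaves a strain variant open, and with 0 arrays of a strain with manf-1 restored, regulation by manf-1 cannot be told apart from it.

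T22F3.11 and alh-5 had differences of -2.03 and -1.79 in mutants under tunicamycin. The 17 intestine markers had a median of -0.24 with 12 below 0. By size alone this argues against a lower share of intestinal RNA as the whole cause. The SE of that median, 0.12, treats the markers as independent and holds no error between arrays, so no test over arrays stands behind this. Scaling between arrays stays open: quantile normalization gave -2.12 and -1.85, at least 1.03 times the differences before it, but it moved differences of all probe sets by a median of only 0.035, so it could not decide. An effect of genotype on these genes under stress may remain as a hypothesis, since the interaction did not pass for either of the probe sets used and the calls rest near the threshold. For T22F3.11 the interaction was -1.68 (limma adjusted p = 0.995), and a second probe set was at -2.47 (0.0974).

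More probe sets passed for tunicamycin in mutants (158) than in wild type (58). The gap depends on the threshold and the fit, with 829 and 782 at an unadjusted p with a 2-fold change and 134 and 20 with only the arrays compared. Without the arrays numbered 2 the ratio of the counts was 2.17, and it lay between 1.52 and 3.96 when single arrays were left out. This ratio cannot decide on a larger spread of those arrays, since both contrasts share 1 estimate of the spread per probe set. The median SD was 0.434 and 0.469 in wild type and 0.400 and 0.373 in mutants, and its part in the gap was not tested. Among 100 drawn splits of arrays between genotypes, 6 gave a gap of 100 or more, the real one included, and the highest other was 148, so chance is not excluded. A larger response of the same genes may contribute but stays open, since the slope of 1.27 lay above 1 by less than 2 of its SE of 0.207.

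For the 4 contrasts of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The tunicamycin contrasts gave 58 and 158 probe sets against at most 0 in the other splits, and 8 and 12 lists against at most 5 and 7. The genotype contrasts gave 1 and 6 probe sets against at most 0 and 1, and 2 and 9 lists against at most 6 and 4. As many lists as the real split came from 4 of the 10 splits for genotype in vehicle and from 1 in the other 3 contrasts, as did the probe set counts in all 4.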

How the results depend on the processing

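Removal of the 4 arrays numbered 2 was chosen after seeing the data. Of 101 gene results in the text, 53 passed, and 25 of these passed under every alternative run for single genes, which were all but the unadjusted p. None of the 53 changed sign. Of the 34 list calls, all kept their direction; 9 held with an estimated correlation. The level of manf-1, planned as a check, gave no value. Signal over background limits dim genes such as tag-244 and drd-1, whose low groups lie among the background controls.

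For tunicamycin in wild type, 58 probe sets became 20 with only the arrays compared, 782 with an unadjusted p and 2-fold change, 22 in the unmoderated test and 35 without the arrays numbered 2. In mutants 158 became 829 with the unadjusted p, 97 unmoderated and 76 without arrays numbered 2. For genotype in vehicle 1 became 493 with the unadjusted p, 0 unmoderated and 0 without arrays numbered 2. For genotype in tunicamycin 6 became 1 without a filter, 11 with the stricter filter, 1 with an offset, 0 without the trend, 1 with robust eBayes, 0 with only the arrays compared, 467 with the unadjusted p, 3 unmoderated and 0 without arrays numbered 2. For the interaction 1 became 610 with the unadjusted p and 0 without arrays numbered 2. Fewer arrays, and for the unmoderated test fewer degrees of freedom, account for part of these losses by construction; otherwise the cause was not tested.

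Lists passing with an estimated correlation were 2, 7, 0, 0 and 0, in the order of contrasts above, against 8, 12, 2, 9 and 3. For genotype in vehicle the mean over a gene's probe sets gave 4 and the removal of arrays numbered 2 gave 0. The cause was not tested.

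Leaving out 1 array gave 41 to 61 probe sets for tunicamycin in wild type, 79 to 178 in mutants, 0 to 2 for genotype in vehicle, 0 to 3 in tunicamycin and 0 to 2 for the interaction. It gave 6 to 13, 11 to 15, 0 to 4, 5 to 10 and 0 to 5 lists, and a slope of 1.13 to 1.33. The vehicle genotype difference of hsp-4, main value 0.05, ranged from -0.38 to 0.28 and was -0.36 without arrays numbered 2. That of hsp-3, main value 0.07, ranged from -0.01 to 0.17. The tunicamycin effect of atf-6 in mutants, main value 0.64, ranged from -0.19 to 1.46 and was -0.21 without arrays numbered 2.

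The labels give replicates only a number: 7 of 18 same-number pairs of arrays had correlated deviations over 0.1. Among arrays of the other groups, 8 of 12 arrays correlated best with one of their own number. The 6 pairs numbered 2 had correlations from 0.054 to 0.23, 4 of them over 0.1, against -0.019 to 0.18 for number 1 and -0.078 to 0.16 for number 3. With their 3′ to 5′ difference given above, the arrays numbered 2 shared a trait that the labels do not explain. For numbers 1 and 3 shared batches stay open. With the replicate block, counts were 64, 189, 1, 3 and 2 probe sets and 10, 14, 2, 9 and 3 lists.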

Other observations

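The scan of 293 gene classes, which are genes sharing the letters before the hyphen, was chosen after seeing the data, and its tests use limma's camera with the preset correlation. In mutants under tunicamycin the vacuolar proton pump subunits (vha) moved down, with 15 of 17 values below 0 (adjusted p = 0.000498), as did the lipl lysosomal lipases with 5 of 5 (adjusted p = 0.00695) and the transthyretin-like ttr genes with 28 of 32 (adjusted p = 0.0159). Translation initiation factors (eif) moved up with 20 of 20 values above 0 (adjusted p = 0.0308). Vacuolar and eif genes passed singly in 0 cases, and ttr in 1. In wild type the sec genes moved up, with 15 of 19 values above 0 (adjusted p = 3.19e-06), and the nspg genes down, with 6 of 6 below 0 (adjusted p = 0.0259). Both classes also passed in mutants in the same direction, sec with 16 of 19 values above 0 (adjusted p = 3.93e-05) and nspg with 5 of 6 below 0 (adjusted p = 0.0011). In mutants compared with wild type under tunicamycin, the lpr genes moved down with 6 of 7 values below 0 (adjusted p = 0.00286) and the myo myosins with 5 of 5 (adjusted p = 0.0456), and for the interaction the histone class moved down with 20 of 25 (adjusted p = 0.00519). None of these class calls held with an estimated correlation. The histone class repeats the histone list, and the lipl and sec classes share members with the lipase and export lists. The myo class shares myo-5 with the pharynx markers. These classes are therefore not separate support.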
